A study of Homo sapiens with 6 samples.

How the data were processed

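RNA was measured by sequencing in 6 libraries of Jurkat cells, an established human T-cell acute lymphoblastic leukemia line. Per the labels, 3 libraries came from cells given DMSO, the solvent control, and 3 from cells given H3B-8800 for 6 hours, a compound that the labels call a splicing inhibitor. Groups and replicate numbers were taken from the sample titles. The labels do not state that the replicates were separate cultures, so every p-value measures the spread between these libraries, which may be technical.

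The deposited table held 1 value per gene and library in CPM, counts per 1000000 reads of the library, as the authors deposited it. Per the submitters' processing notes, the tools named were bcl2fastq, TopHat, HTSeq and edgeR, and the genome build was hg19. Their versions and settings were not given in the sources used here. The sample protocol describes poly-A selected, strand-specific, single-read libraries, whereas the series text describes unstranded, paired-end libraries. Whether counting used strand was therefore open, and levels of genes that overlap another gene are uncertain. Short reads from genes with near-identical copies, among them ribosomal protein genes with their processed pseudogenes, could be split or discarded by the counting, so these levels are uncertain too.

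The table was a selection and not a transcriptome. It held 1875 genes, each above 100 CPM in at least 1 library, and its rows stood in 2 blocks, 720 genes with a lower mean under H3B-8800 followed by 1155 with a higher mean. On the log2 scale used here, no gene lay between -0.30 and 0.07, so the band without genes was not centred on 0 and its midpoint was -0.11. The rule by which the authors chose these genes was not given in the sources used here. Counts of changed genes are therefore counts within a list that the study chose on these same libraries, and they are not independent evidence of a change or of its direction. In 5 rows the gene name had become a calendar date, and these were tested but not named.

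Depth was read from the values. Within each library, 100% of CPM values were whole multiples of 1 step, within a tolerance of 0.01, and this step was taken as the value of 1 read. By this estimate 1 CPM stood for 40.9, 43.8 and 30.3 reads in DMSO replicates 1 to 3 and 43.2, 35.6 and 39.1 reads in H3B-8800 replicates 1 to 3. No value lay near a single read, so the step could not be checked at low counts, and the reads were used for depth only. On this estimate the lowest value in a library rested on 772 to 2140 reads, for a counting error of 2.16% to 3.60%. The median SE of a log2 change was 0.061. Reads are not independent molecules, so this error covers counting only. The table held 46.1% to 50.3% of each library's reads. Replicates were compared by chi-square on these reads. The chi-square per degree of freedom was 12.07 to 147.42 over the pairs within groups, so no library was a repeat of another within sampling noise.

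The planned count test was replaced by the test planned for normalized values, because the unit was CPM and the reads derived from its steps were an estimate. Values were tested as log2(CPM + 1) with limma 3.58.1 in R 4.3.3, with an intensity trend on the prior variance and the group as the only term. Fold changes are on this scale and understate the change of low genes slightly. P-values were two-sided and adjusted by Benjamini-Hochberg over the 1875 genes, with a threshold of 0.05. A gene rose or fell where it passed this threshold. Means are given with the SD over 3 libraries.

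Before the data were examined, 31 gene lists with 1113 genes were written for a T-cell leukemia line given a splicing inhibitor. They covered SF3b and the U2 snRNP, SR proteins and their kinases, hnRNP proteins, other spliceosome components, replication-dependent histones, other intronless genes, immediate early genes and p53 targets. They also covered the integrated stress response, the unfolded protein response, heat shock proteins, apoptosis regulators, the G2 and M phases, DNA replication, DNA repair, the NOTCH1 and MYC program and T cell identity. The rest were ribosomal proteins, the proteasome and ubiquitin, small nucleolar RNA host genes, nonsense-mediated decay factors, cholesterol synthesis, NF-kB and cytokine genes, the interferon response, a sample of KRAB zinc finger genes, mitochondrially encoded genes, oxidative phosphorylation and markers of B cells, myeloid cells, fibroblasts with epithelium, and erythroid cells. The table held 369 of these genes, and 20 lists had at least 3 members in it.

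Each of these 20 lists was tested with camera (limma) at a preset correlation of 0.01 and at an estimated correlation, and with fry (limma). A two-sided Fisher's exact test compared members with changes above and below 0, whether or not they passed the threshold, with all other tabulated genes. It treats genes as independent, so its p-values are too small where members vary together. P-values were adjusted by Benjamini-Hochberg over the 20 lists. Camera compares a list with the other tabulated genes, whereas fry asks whether a list's genes moved, on balance, one way and compares them with no others.

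Genes were named by a rule fixed before the data were examined. It took the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap, passing over clone, LOC and LINC names. It also took up to 4 members per list by smallest p, and SF3B1, SRSF6, USP7, MYC, MCL1 and NOTCH1 whatever their values. MYC and MCL1 were not listed in the table. The rule gave 101 genes, of which 1 is not reported here.

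Settings varied by a plan made before the data were examined were a fit with the replicate number as a block, leaving out each library in turn, pseudocounts of 0.1 and 5, a filter at the lower quartile of the mean level, centring each library to the table median, limma without the trend, a minimum log2 change of 1, and camera with an estimated correlation. Added after the data were seen were a scale on which the ribosomal protein genes had equal medians in every library, the total without mitochondrial reads, and removal of each library's linear trend on GC content and transcript length. No spike-in was used here and no gene known to be unchanged was in the table, so the deposited scale could not be checked against an outside standard.

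Intron number, mature transcript length and GC content came from GENCODE release 29 on another genome build than the authors used, so they were matched by gene symbol and no coordinates were taken. Symbols matched directly for 1808 genes and through an older symbol for 1, and 96.5% of tabulated genes had values. Relations to these properties were computed over 1793 protein-coding nuclear genes with 2000 bootstrap draws and 10000 permutations. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps and the figures.

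The limma steps were tested on simulated data for the 1875 tabulated genes in 20 simulations. They recovered 3.5% of genes changed by 0.1 on the log2 scale, 56.0% at 0.25, 90.5% at 0.5 and 99.3% at 1. Of the calls, 4.8% were genes simulated as unchanged. Most genes were left unchanged in each simulation, whereas 1774 of the 1875 passed in the data. The adjusted threshold was therefore stricter in the simulations, and these rates do not carry over to the data. Camera found 100% of 20-gene sets raised by 0.3 on the log2 scale, and 2.75% of unchanged sets had a p under 0.05. No gene outside the raised set was changed there, whereas most tabulated genes passed the threshold in the data. The 100% therefore does not carry over to the lists tested here. Genes were simulated as independent of each other and the sets were drawn at random. These rates therefore do not cover lists whose members vary together, as those of real libraries can.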

Results

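The series asked how treatment with H3B-8800, a small molecule that binds the splicing factor SF3B1, altered gene expression in T-cell leukemia. Expression was given in CPM for 3 libraries of Jurkat cells with DMSO and 3 libraries after 6 hours of H3B-8800. By the steps of the values, 1 CPM stood for about 30.3 to 43.8 reads, depending on the library. The table was a list of 1875 genes that the study chose on these samples, and transcript isoforms were not part of it.

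Within this list, 1054 genes rose after H3B-8800, 720 fell and 101 did not pass the threshold (limma, Benjamini-Hochberg adjusted p of 0.05). The largest rise was that of DDX39B, an RNA helicase of splicing and mRNA export, from 86.2 ± 16.3 to 271 ± 22.0 CPM (SD, n = 3 per group), a log2 change of 1.66. The largest fall was that of UBA2, a subunit of the SUMO-activating enzyme, from 238 ± 9.72 to 56.5 ± 3.13 CPM, a log2 change of -2.06. Of 24 tabulated genes of DNA replication 19 fell and 4 rose, and all 73 tabulated ribosomal protein genes rose. Camera (limma) called these 2 lists with its preset correlation, with neither call kept at adjusted p = 0.433 and 0.555 with an estimated correlation. SF3B1 rose, whereas the SR protein gene SRSF6 and the deubiquitinase gene USP7 fell.

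The median log2 change was -0.67 among genes that fell (quartiles -0.91 and -0.49) and 0.38 among genes that rose (quartiles 0.27 and 0.53). The table listed rises from 0.07 but no fall smaller than -0.30, so these medians do not compare the sizes of rises and falls. By at least 1 on the log2 scale, 26 genes rose and 136 fell. The groups did not overlap in 1762 genes, or 94.0% of the table. Chance gives 10% for 3 libraries against 3, but only for genes not chosen on those libraries, so 10% is no standard for this list. The 1774 calls were the same number at an unadjusted p of 0.05. Because the study chose the list on these samples, neither the counts nor the sizes were independent evidence of a change or of a direction.

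The split of rises and falls rested on the scale. With each library scaled to equal medians of the ribosomal protein genes, an alternative added after the data were seen, the median change of all tabulated genes went from 0.20 to -0.21, 183 genes rose and 949 fell. Counts of members are therefore given on both scales for the groups below, the deposited one first.

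**Figure D1:**
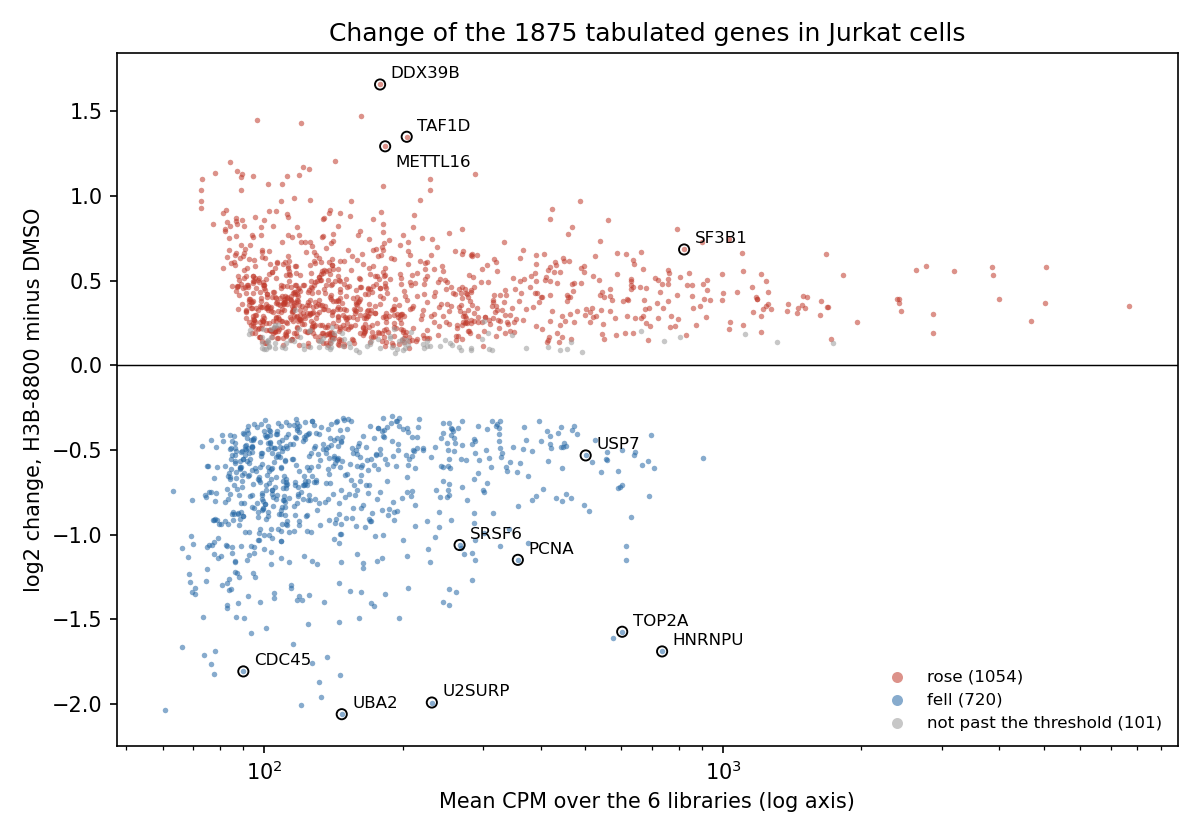
The log2 change of each of the 1875 tabulated genes (H3B-8800 minus DMSO) is plotted against its mean CPM over 6 libraries on a log axis, with 1054 genes that rose in red, 720 that fell in blue and 101 not past the threshold in gray. No gene lay between -0.30 and 0.07, and on the scale set by ribosomal protein genes 183 rose and 949 fell.

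After DDX39B, the largest rises were those of PCNXL3 (1.47 on the log2 scale), the JNK scaffold gene MAPK8IP3 (1.45), NRROS (1.43) and TAF1D (1.35). METTL16, which encodes an RNA methyltransferase, rose from 106 ± 4.83 to 261 ± 4.12 CPM. PRPF3, a component of the U4/U6 snRNP, rose from 85.9 ± 2.93 to 200 ± 7.92 CPM, and the ubiquitin ligase gene TRIM11 from 50.6 ± 2.62 to 118 ± 0.844 CPM. These 8 genes also rose on the scale set by ribosomal protein genes.

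After UBA2, the largest falls were those of the kinase gene SLK (-2.03), the mitochondrial malic enzyme gene ME2 (-2.00) and U2SURP (-1.99), which encodes a protein associated with the U2 snRNP. U2SURP went from 371 ± 52.3 to 92.3 ± 9.75 CPM. The nucleoporin gene NUPL1 (-1.96) and RBM12 (-1.87) followed. CTPS1, which makes CTP, fell from 228 ± 8.51 to 63.5 ± 4.10 CPM, and PRPS2, which makes the sugar phosphate for nucleotide synthesis, from 121 ± 9.97 to 33.6 ± 1.47 CPM.

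Of the genes fixed in advance from the study's subject, SF3B1 rose from 631 ± 35.0 to 1014 ± 14.5 CPM, a log2 change of 0.68 (SE 0.057, limma adjusted p = 1.14e-05). SRSF6 fell from 361 ± 26.1 to 172 ± 8.12 CPM, a log2 change of -1.06 (SE 0.064, limma adjusted p = 2.49e-06). USP7 fell from 593 ± 29.6 to 410 ± 7.51 CPM, a log2 change of -0.53 (SE 0.052, limma adjusted p = 2.65e-05). On the scale set by ribosomal protein genes these changes were 0.27, -1.47 and -0.95 in the order given, each past the threshold. NOTCH1, often mutated in this leukemia, was at 187 ± 21.7 and 215 ± 2.91 CPM, with a log2 change of 0.21 (limma adjusted p = 0.0312). That call was lost on leaving out any library but DMSO replicate 2, where adjusted p reached 0.0650 to 0.101, and the change was -0.21 on the scale set by ribosomal protein genes. MYC and MCL1 were not listed in the table.

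**Figure D2:**
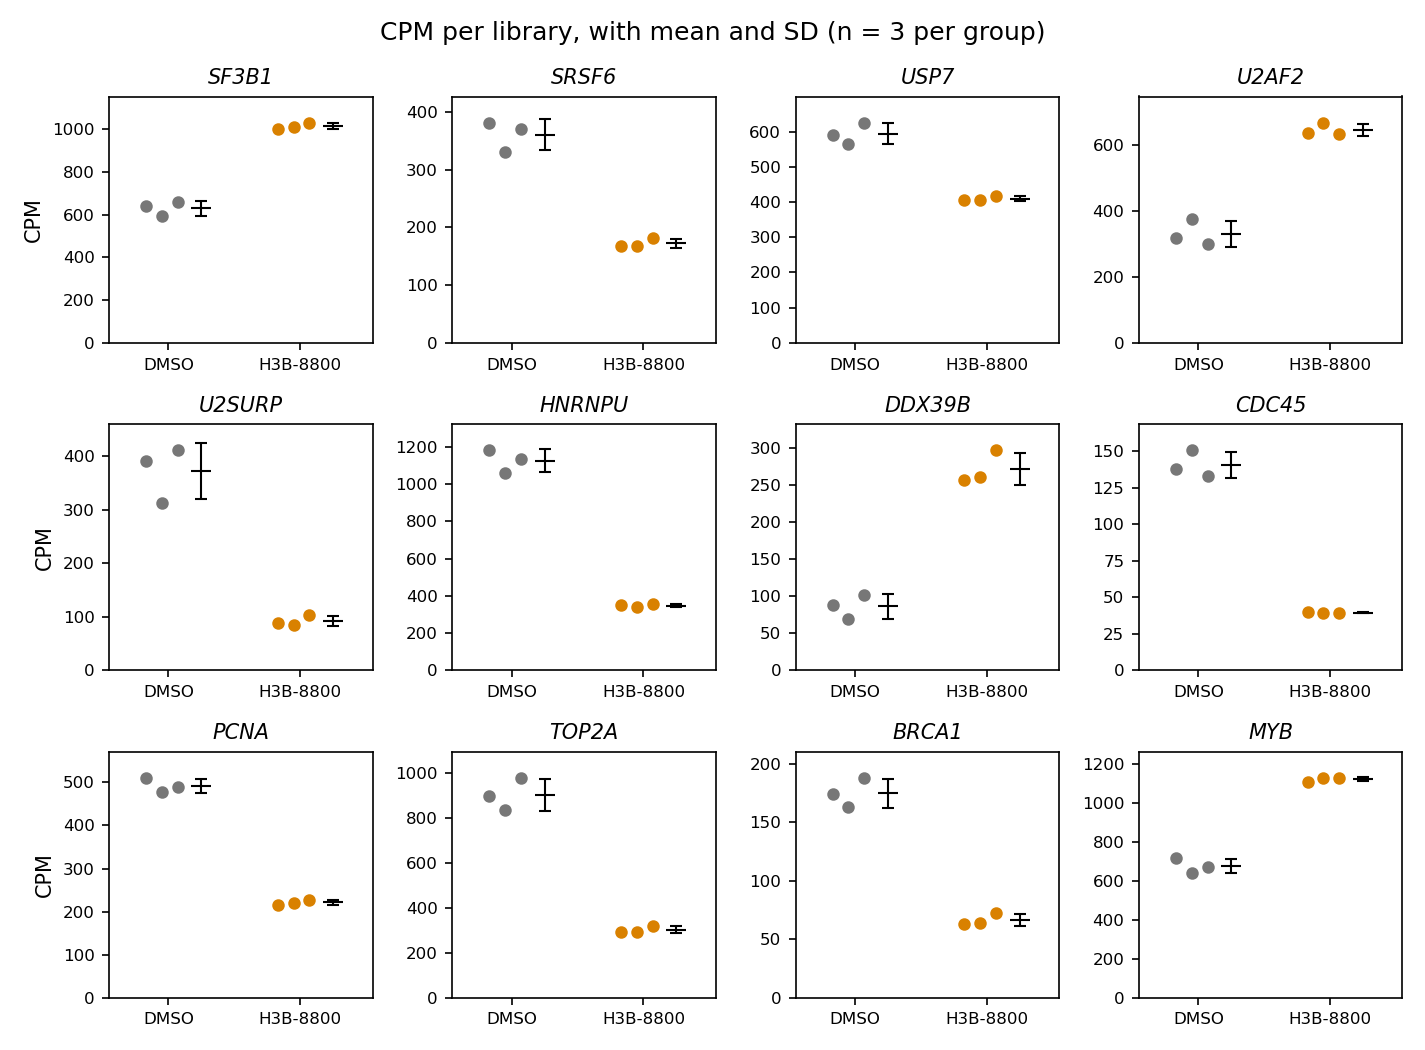
CPM of 12 genes is shown for each of 3 DMSO libraries (gray) and 3 H3B-8800 libraries (orange), with the mean and SD beside the points and axes that start at 0. The groups did not overlap in any of these genes, with SF3B1 at a mean of 631 against 1014 CPM and SRSF6 at 361 against 172 CPM.

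Genes of the splicing machinery moved in both directions. Of 16 tabulated genes of SF3b and the U2 snRNP, the part of the spliceosome that recognises the branch point, 12 rose, 3 fell and 1 did not pass, with 15 past the threshold adjusted over the list alone; on the scale set by ribosomal protein genes 4 rose and 6 fell. U2AF2, which binds the polypyrimidine tract, rose from 331 ± 39.5 to 646 ± 18.4 CPM, whereas DDX42 fell from 224 ± 4.64 to 118 ± 3.57 CPM and DNAJC8 from 246 ± 8.11 to 167 ± 3.01 CPM. Of 16 genes of SR proteins and their kinases, 12 rose, 2 fell and 2 did not pass, with 14 past the threshold adjusted over the list alone; on the other scale 3 rose and 4 fell. The falling members were SRSF6 and SRPK1, an SR protein kinase (-0.74), while SRRM1 (0.98) and SON (0.80) rose.

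Among 20 hnRNP genes, which encode RNA-binding proteins of pre-mRNA, 11 rose and 9 fell, and all 20 passed adjusted over the list alone; on the other scale 3 rose and 11 fell. HNRNPU fell from 1125 ± 62.2 to 348 ± 7.45 CPM and HNRNPAB from 443 ± 6.41 to 211 ± 3.77 CPM, with smaller falls of HNRNPM (-0.63) and HNRNPD (-0.62). Of 36 other spliceosome components, 25 rose, 9 fell and 2 did not pass, with 34 past the threshold adjusted over the list alone; on the other scale 8 rose and 13 fell. PRPF3 and LUC7L (0.89) rose, and EFTUD2, a GTPase of the U5 snRNP (242 ± 16.7 to 120 ± 2.87 CPM), and the branch point binding gene SF1 (263 ± 12.8 to 157 ± 2.64 CPM) fell. None of these 4 lists stood apart from the other tabulated genes by camera, with adjusted p = 0.209, 0.131, 0.722 and 0.198 in the order given, or by Fisher's exact test, with adjusted p = 0.209, 0.0941, 0.704 and 0.209. In the hnRNP list the median was 0.16, while the mean of -0.06 and camera's direction were negative.

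Genes of DNA replication and the S phase fell. Of 24 in the table, 19 fell, 4 rose and 1 did not pass, with 23 past the threshold adjusted over the list alone, and the median log2 change was -0.65; on the scale set by ribosomal protein genes 20 fell and 1 rose. CDC45, part of the replicative helicase, fell from 140 ± 9.03 to 39.4 ± 0.415 CPM and the clamp loader gene RFC1 from 186 ± 7.69 to 63.7 ± 1.83 CPM. PCNA, the sliding clamp, fell from 492 ± 16.5 to 222 ± 5.72 CPM and MCM4 from 506 ± 14.8 to 244 ± 1.61 CPM. The list stood below the other tabulated genes by camera (adjusted p = 5.07e-04) and had more falling members by Fisher's exact test (adjusted p = 5.87e-04). Camera's call was lost with an estimated correlation (adjusted p = 0.433 with an estimated correlation).

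Genes of the G2 and M phases went both ways, with 16 of 36 rising, 18 falling and 2 not past, and 34 past the threshold adjusted over the list alone. TOP2A, the topoisomerase of mitotic chromosomes, fell from 903 ± 72.1 to 302 ± 15.1 CPM, and NCAPH (-0.91), NCAPG (-0.82) and CKAP5 (-0.74) fell as well. Of 16 DNA repair genes, 6 rose, 8 fell and 2 did not pass, with 14 past the threshold adjusted over the list alone. BRCA1 fell from 175 ± 12.4 to 66.4 ± 5.12 CPM and FANCI from 374 ± 20.7 to 172 ± 5.87 CPM, and RBBP8 (195 ± 15.3 to 97.1 ± 4.60 CPM) and PRKDC (-0.77) fell too. Camera gave adjusted p = 0.341 and 0.320 for these lists, and Fisher's exact test gave adjusted p = 0.257 and 0.517. Their medians of -0.13 and -0.19 became 0.01 and 0.04 once each library's GC and length trend was removed, and on the scale set by ribosomal protein genes 1 and 0 members rose against 21 and 10 that fell.

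Ribosomal protein genes rose in 73 of 73 tabulated cases, all of them past the threshold adjusted over the list alone, by 0.19 to 0.78 on the log2 scale with a median of 0.43. RPS15A rose from 334 ± 3.79 to 494 ± 13.8 CPM, RPL31 from 684 ± 44.0 to 999 ± 5.66 CPM, RPL17 from 89.9 ± 7.15 to 135 ± 2.48 CPM and RPL29 from 399 ± 35.1 to 597 ± 19.2 CPM. Together the 73 genes took 5.01 ± 0.389% of reads under DMSO and 6.71 ± 0.203% under H3B-8800. The list stood above the other tabulated genes by camera (adjusted p = 3.50e-06), a call lost with an estimated correlation (adjusted p = 0.555 with an estimated correlation). It also stood above them by Fisher's exact test (adjusted p = 5.24e-15). That test takes the 73 genes as independent, so its p-value overstates the evidence where they vary together. On the scale set by these genes themselves 9 rose and 3 fell, with a median of 0.02 by construction, and with the GC and length trend of each library removed 58 rose and 3 fell, with a median of 0.27. Their share of reads was 5.46% in DMSO replicate 2 against 4.78% and 4.79% in the other DMSO libraries, and that library also correlated less with them (0.980 and 0.978, across genes) than they did with each other (0.994).

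All 12 tabulated mitochondrially encoded genes rose, also adjusted over the list alone, with a median of 0.56; on the scale set by ribosomal protein genes none of them passed. MT-CYB, for cytochrome b, went from 1315 ± 288 to 2042 ± 117 CPM, with similar rises of MT-CO2 (0.56), MT-ND1 (0.52) and MT-ATP6 (0.54). They took 1.97%, 1.65% and 2.80% of reads in DMSO replicates 1 to 3 and 3.26%, 2.92% and 3.07% in the H3B-8800 libraries. For these genes camera gave adjusted p = 0.165 and, without DMSO replicate 3, adjusted p = 0.0134 with a median of 0.76; over the settings tried with the preset correlation it was 0.0111 to 0.223, the lowest being that on the scale set by ribosomal protein genes, where the median was 0.14. It had adjusted p = 0.700 with an estimated correlation. Fisher's exact test gave adjusted p = 0.0241.

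Of 26 nuclear genes of oxidative phosphorylation, 20 rose, 4 fell and 2 did not pass, with 24 past the threshold adjusted over the list alone; on the other scale 0 rose and 7 fell. With the GC and length trend removed, 12 of 25 rose and 6 fell, and the median went from 0.32 to 0.15. COX7C (0.45) and ATP5E (0.35) rose, and both rises were lost on the scale set by ribosomal protein genes, where ATP5E stood at -0.06. SDHA, the flavoprotein of succinate dehydrogenase, fell from 124 ± 13.5 to 51.5 ± 0.439 CPM. NDUFS1 fell as well (-0.37), a call lost with the GC and length trend removed (-0.05). The list had adjusted p = 0.132 by camera and adjusted p = 0.0497 by Fisher's exact test.

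**Figure D3:**
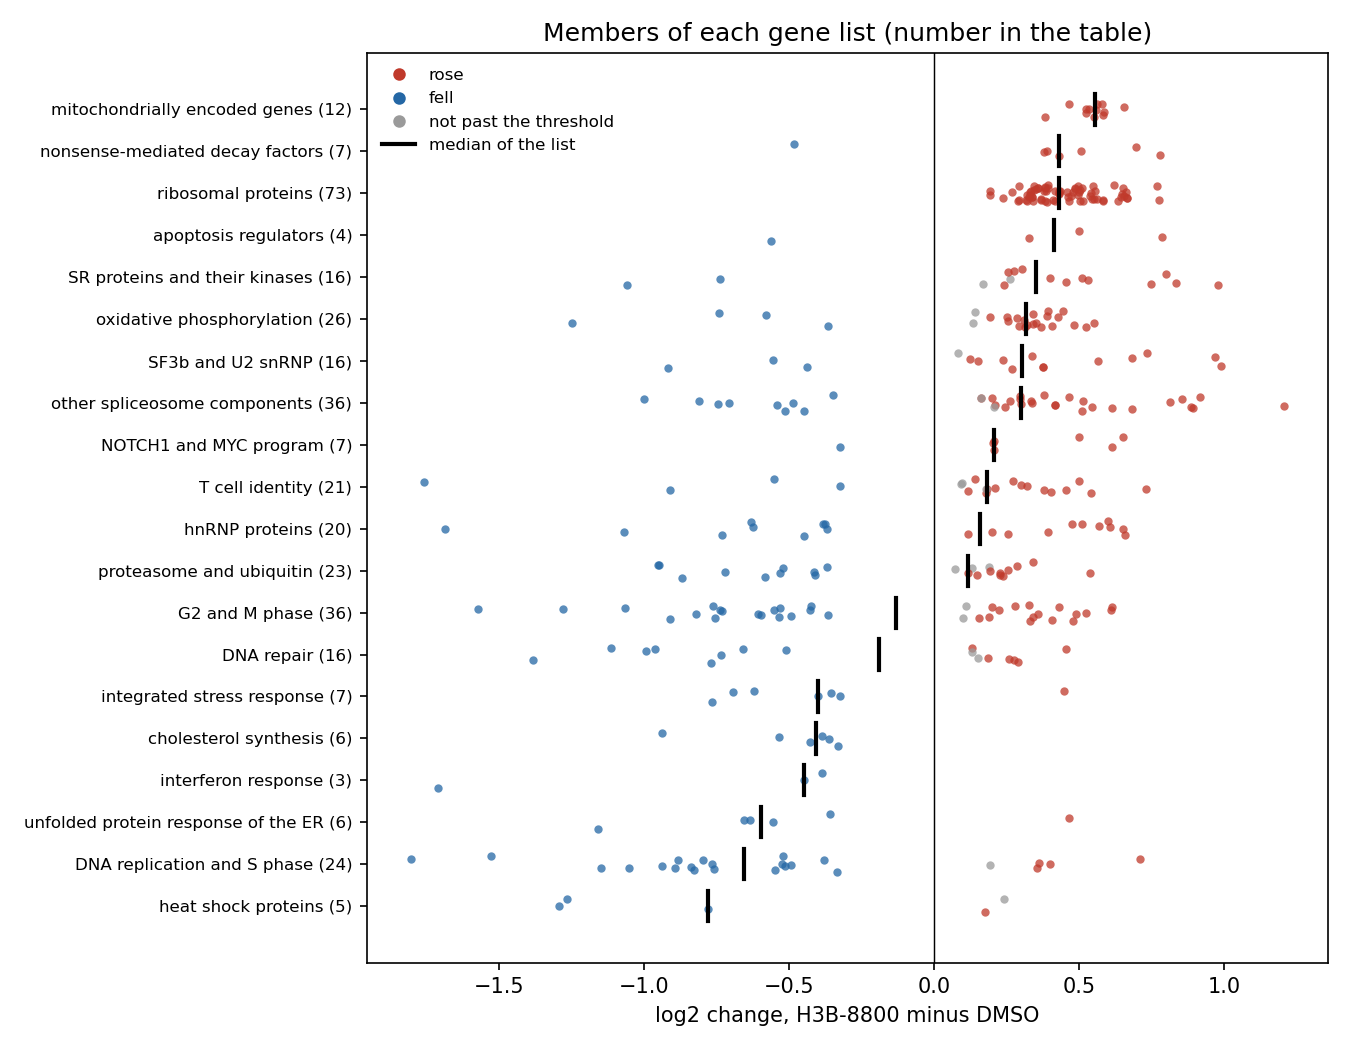
The log2 change (H3B-8800 minus DMSO) of each tabulated member is shown for the 20 lists with at least 3 members, with the list median as a black bar. All 73 ribosomal protein genes and 12 mitochondrially encoded genes lay above 0, and 19 of 24 DNA replication genes fell; on the scale set by ribosomal protein genes the first group had a median of 0.02 and the second of 0.14.

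Stress-related lists held few tabulated genes, and most of these fell. Of 7 genes of the integrated stress response, 6 fell and 1 rose, among them the serine synthesis gene PSAT1 (378 ± 8.95 to 233 ± 1.54 CPM), SHMT2 (-0.77), whose product converts serine to glycine, the asparagine synthetase gene ASNS (-0.62) and the tryptophan tRNA synthetase gene WARS (-0.36). Of 6 genes of the unfolded protein response, 5 fell and 1 rose, with HYOU1, a chaperone of the endoplasmic reticulum, at 318 ± 24.5 and 142 ± 3.55 CPM, and falls of PDIA6 (-0.66), SEL1L (-0.64) and HSP90B1 (-0.56). Of 5 heat shock genes, 3 fell, 1 rose and 1 did not pass. HSPH1 (-1.27), CHORDC1 (-1.29) and STIP1 (-0.78) fell, while HSPA4 rose by 0.18, or by 0.37 with the GC and length trend removed. The HSPA4 change was -0.24 on the scale set by ribosomal protein genes and lost its call without H3B-8800 replicate 2. On the scale set by ribosomal protein genes none of these genes rose, and 6, 5 and 4 fell in the order of the lists. Adjusted over the list alone, 7, 6 and 4 genes passed, and camera gave adjusted p = 0.0972, 0.110 and 0.243. Fisher's exact test gave adjusted p = 0.0497, 0.0941 and 0.473.

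All 6 tabulated genes of cholesterol synthesis fell, also adjusted over the list alone and on the scale set by ribosomal protein genes. IDI1 fell from 106 ± 12.2 to 54.7 ± 3.09 CPM, and INSIG1 (-0.53), the transcription factor gene SREBF2 (-0.43) and ACAT2 (-0.36) fell by less. Camera gave adjusted p = 0.0532, which became 0.0390 without DMSO replicate 2 and 0.0359 without DMSO replicate 3, in a range of 0.0359 to 0.0749 over the settings tried with the preset correlation. The list had adjusted p = 0.433 with an estimated correlation. Fisher's exact test gave adjusted p = 0.0211. The 3 tabulated interferon response genes fell, all past the threshold adjusted over the list alone and on both scales: PARP14 from 114 ± 7.46 to 34.0 ± 1.21 CPM, XAF1 by less (-0.45) and IRF1 (-0.39). Camera gave adjusted p = 0.132 for this list and Fisher's exact test adjusted p = 0.126.

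Proteasome and ubiquitin genes split evenly, with 10 of 23 rising, 10 falling and 3 not past, and 20 past the threshold adjusted over the list alone; on the other scale 0 rose and 17 fell. PSMA5 fell from 219 ± 10.2 to 113 ± 1.79 CPM, PSME3 from 281 ± 4.84 to 145 ± 2.69 CPM and PSMC5 by 0.87 on the log2 scale. The median was 0.12, and 0.02 with the GC and length trend removed, while the mean of -0.15 and camera's direction were negative (adjusted p = 0.376), and Fisher's exact test gave adjusted p = 0.704. Of 7 nonsense-mediated decay factors, 6 rose and 1 fell, all past the threshold adjusted over the list alone; on the other scale 2 rose and 1 fell. SMG5 rose on both scales, from 181 ± 4.96 to 294 ± 6.81 CPM, whereas the rises of RNPS1 (0.43) and CASC3 (0.39) did not pass on the scale set by ribosomal protein genes, where CASC3 stood at -0.03. By camera the list had adjusted p = 0.149, and by Fisher's exact test adjusted p = 0.348.

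Of 21 genes of T cell identity, 14 rose, 4 fell and 3 did not pass, with 18 past the threshold adjusted over the list alone; on the scale set by ribosomal protein genes 1 rose and 11 fell. CD1E, a lipid-presentation gene of immature T cells, fell from 196 ± 2.89 to 57.2 ± 2.58 CPM and CD1A from 101 ± 1.46 to 53.2 ± 0.532 CPM, while the transcription factor gene MYB rose from 677 ± 37.2 to 1122 ± 10.9 CPM. Of 7 genes of the NOTCH1 and MYC program, 6 rose and 1 fell, all past the threshold adjusted over the list alone; on the other scale 2 rose and 2 fell. NOTCH2 (0.61), the NOTCH target DTX1 (0.65) and LEF1 (0.50) rose, the last without passing on the other scale, and TCF7 fell (-0.33). Camera gave adjusted p = 0.257 and 0.256 for these lists, and Fisher's exact test adjusted p = 0.147 and 0.348.

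Of 4 apoptosis regulators, 3 rose and 1 fell, all past the threshold adjusted over the list alone; on the other scale 1 rose and 1 fell. CASP2 rose from 133 ± 7.44 to 229.5 ± 9.55 CPM on both scales. BCL2L1, which encodes an inhibitor of cell death, rose by 0.50 and BIRC5 by 0.33, calls that were lost on the scale set by ribosomal protein genes, where BIRC5 stood at -0.09. BIRC6 fell (-0.56). The list had adjusted p = 0.402 by camera and adjusted p = 1 by Fisher's exact test.

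Lists with under 3 tabulated members were not tested as lists. RELA, a subunit of NF-kB, rose from 59.4 ± 7.10 to 130 ± 3.09 CPM, and the snoRNA host gene TAF1D rose from 116 ± 27.5 to 292 ± 25.1 CPM. TAF7, an intronless gene (0.51), GNB2L1, another snoRNA host (0.31), and the immediate early genes PIM3 (0.42) and ZFP36L2 (0.22) rose as well. None of these 4 rises passed on the scale set by ribosomal protein genes, where GNB2L1 stood at -0.11 and ZFP36L2 fell (-0.20), and PIM3 stood at -0.07 with the GC and length trend removed. The KRAB zinc finger gene ZNF107 fell (-0.56), a call lost with that trend removed (-0.16). All members of these lists passed adjusted over the list alone. The lists of replication-dependent histones and of p53 targets had no tabulated member.

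Markers of other cell types were nearly missing from the table, with 0 tabulated markers of B cells, fibroblasts with epithelium or erythroid cells and 1 of myeloid cells. That marker, AIF1, was at 129.5 ± 11.6 and 148 ± 7.40 CPM (0.19, limma adjusted p = 0.0344), passed adjusted over the list alone, and stood at -0.22 on the scale set by ribosomal protein genes. Its call was lost without DMSO replicate 1, H3B-8800 replicate 1 or H3B-8800 replicate 2, and with the GC and length trend removed its change was 0.0062. A table of selected genes above 100 CPM cannot show markers at a lower level.

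By fry, which compares a list with no other genes, 19 of the 20 lists moved one way on balance at an adjusted p of 0.05. Mitochondrially encoded genes were the exception (fry, adjusted p = 0.0696). The table was a selection with no change between -0.30 and 0.07, so fry's calls do not set a list apart. They included lists that went both ways, such as hnRNP genes with 11 rising and 9 falling (fry, adjusted p = 0.0153). Both fry and Fisher's exact test were run on the deposited scale only. Fisher's exact test counts changes above and below 0, and these counts depend on the scale. Camera called 2 of 20 lists with its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.433, and Fisher's exact test called 6 lists.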

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

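The scale set by ribosomal protein genes, the total without mitochondrial reads and the removal of each library's GC and length trend were chosen only after the data were seen; the other settings were planned. Leaving out 1 library gave 1664 to 1811 changed genes, 945 to 1091 that rose and 717 to 720 that fell, against 1774, 1054 and 720. A minimum log2 change of 1 left 162, 26 and 136, by its own construction. Keeping 1406 genes at or above the lower quartile of mean level left 465 falling genes, with fewer genes tested. Scaling to the ribosomal protein genes gave 1132 changed genes, of which 183 rose, and 903 of the main calls kept their direction; its construction lowered every change. On that scale the change turned to -0.20 in ZFP36L2, -0.24 in HSPA4, -0.087 in BIRC5, -0.11 in GNB2L1, -0.026 in CASC3, -0.061 in ATP5E, -0.22 in AIF1 and -0.21 in NOTCH1, and 13 further named genes lost their call. With the GC and length trend removed, 1607 of 1797 genes with structure values passed, 875 up and 732 down, and PIM3 stood at -0.067 and NOTCH1 at -0.0096; the cause was not tested. Pseudocounts, centring, limma without the trend and the total without mitochondrial reads kept each named gene's direction and call. Camera called 2 lists, 2 to 4 on leaving out 1 library (4 without DMSO replicate 3, with cholesterol synthesis and mitochondrially encoded genes added; 3 without DMSO replicate 2), 4 under the quartile filter (cholesterol synthesis and the unfolded protein response added), 3 on the scale set by ribosomal protein genes (mitochondrially encoded genes added), 3 with the GC and length trend removed (cholesterol synthesis added) and 0 with an estimated correlation; the cause was not tested. With the replicate number as a replicate block, 1826 genes passed, 1772 of the main calls kept their direction, and no named gene or list changed its call. The series text speaks of matched pairs without tying them to the numbers. Deviations of same-numbered libraries from their group means correlated at -0.07, 0.63 and 0.58 across genes: replicates 2 and 3 of DMSO correlated best with their own number, but DMSO replicate 1 with H3B-8800 replicate 3 (0.46), so the numbers were not taken to pair the libraries. Depth was not limiting, since the estimated counting error was at most 3.60%.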

Other observations

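The grouping of genes by symbol, the test of GC content and length for the intron relation, both tests on ribosomal protein genes, the GC and length slopes without DMSO replicate 2 and the test for H3B-8800 RNA in DMSO replicate 2 were chosen only after the results were seen.

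Beyond the fixed lists, tabulated genes were grouped by the letters that open their symbols, which gave 36 families of at least 6 genes, and the members named here were chosen after their values were seen. Of 10 nucleoporin genes whose symbols begin with NUP, 7 fell and 3 rose, with a median of -0.64; on the scale set by ribosomal protein genes 7 fell and 1 rose, and with the GC and length trend removed 7 fell and 3 rose. NUP133 went from 150 to 67.4 CPM (-1.14) and NUP155 from 146 to 70.8 CPM (-1.04), whereas NUP62 rose (0.66). Of 10 deubiquitinase family genes beginning with USP, 7 fell and 3 rose, and 7 fell under each of these added settings. USP24 (-1.32) and USP9X (-1.23) fell by more than USP7 (-0.53). Of 7 vesicle sorting genes beginning with VPS, 6 fell and 1 rose, led by VPS13C (229 to 99.1 CPM), and 6 and 5 fell under the added settings.

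Of 18 zinc finger genes beginning with ZNF, 15 rose and 3 fell, although 6 rose and 4 fell on the scale set by ribosomal protein genes. With the GC and length trend removed, 13 of 17 rose and 2 fell. ZNF263 rose from 74.2 to 163 CPM and ZNF646 from 55.9 to 123 CPM. Histone demethylase genes beginning with KDM rose in 8 of 9 cases, with KDM6B highest (0.83), but in 4 of 9 on the other scale. With the GC and length trend removed, 8 of these 9 rose and 1 fell. All 9 nuclear COX genes rose, 0 did on the other scale, and 4 rose and 1 fell with the GC and length trend removed. By Fisher's exact test against all other tabulated genes, 2 of the 36 families passed Benjamini-Hochberg adjustment, the symbols beginning with RPL and with RPS, the latter including the kinase gene RPS6KA3. The adjusted p was 0.263 for both NUP and USP, 0.111 for VPS and COX, 0.379 for ZNF and 0.460 for KDM, so these counts are descriptions of members.

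Genes that fell had more introns than genes that rose, with medians of 16 and 8 over 694 and 1000 genes (permutation p = 1e-04, the smallest that 10000 permutations can give). The share that fell climbed from 9.9% of 101 genes with 0 to 2 introns to 69.8% of 341 genes with over 20. In a joint fit with GC content, length and level, the slope was -0.2528 per doubling of introns + 1 (95% bootstrap interval -0.2783 to -0.2268, across genes, which are not independent), and -0.2571 without DMSO replicate 2. The largest intron slope between libraries of 1 group was 0.1342 of that between groups. It came from the same joint fit, which takes out linear GC and length trends. Its small size therefore could not decide on such trends. The slope between groups, with both terms in the fit, argues against a linear GC and length trend as the whole cause. A bias shared by all libraries of 1 group would not show in the slopes within groups, and such a bias of another form stays open. A dependence of these transcripts on splicing is a candidate explanation that stays open, as does the unknown rule by which the table was chosen.

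Genes that rose also had a higher GC content (50.2% against 44.7% in medians) and shorter transcripts (3043 against 4277 nt) than genes that fell, each with a permutation p = 1e-04, the smallest possible. In the joint fit with introns, GC content and level the length slope had the opposite sign, 0.0874 (95% interval 0.0612 to 0.1142). Similar slopes appeared inside the DMSO group: the largest within-group slope was 0.7665 of the slope between groups for GC content and 0.6016 for length, both involving DMSO replicate 2. Without that library the slopes between groups went from 0.2729 to 0.3411 per 10 percentage points of GC and from -0.1357 to -0.1627 per doubling of length, so its own trend did not produce these relations, and the largest within-group slopes were 0.1779 and 0.2938 of them. A bias shared by the libraries of 1 group was not tested and stays open. For DMSO replicate 2, the displacement in mitochondrially encoded genes was -132.7% of the H3B-8800 effect (SD 65.9 over 12 genes), below 0 by more than that SD. The median displacement was 13.4% in other rising genes (SD 54.0 over 1042 genes) and 9.2% in falling genes (SD 30.3 over 720 genes). Both shares thus varied widely between genes. Mitochondrially encoded genes took 1.97% and 2.80% of reads in DMSO replicates 1 and 3, so their level also varied between the other DMSO libraries. The SD over genes leaves this out, so the test could not decide on a share of H3B-8800 RNA in DMSO replicate 2. Removing the GC and length trend kept 16.42% of that library's displacement along the effect, so such a trend stays open for that library.

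The joint rise of ribosomal protein genes could reflect a shared scale factor, for example fewer other transcripts per cell, or a change of these genes themselves. The rise was not compared with that of other genes with as many introns. Tabulated genes with 0 to 2 and 3 to 5 introns, ribosomal protein genes not set aside, had median changes of 0.402 and 0.338. Removing the GC and length trend lowered the median of the ribosomal protein genes to 0.27. A shared factor alone was argued against for the differences among members: their SD beyond error was 0.1044 (95% interval 0.077 to 0.126), wholly above the 0.05 that such a factor allowed, although it reached below the stricter bound of 0.1. With library medians removed, the sum of squared deviations of the members from their mean, divided by their pooled squared error, was 199.4 over 73 genes. This sum lies near the number of genes when members share 1 change. For the part that the members share, a median of 0.4323, the scale factor and a change of these genes cannot be told apart, because no gene known to be unchanged was in the table. The empty band of the table from -0.30 to 0.07 had its midpoint at -0.11, below 0, whereas the scale set by ribosomal protein genes lowered changes, so the authors' selection did not sit symmetrically on either scale.

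The 6 libraries can be split into 3 and 3 in only 10 ways, so no share under 0.1 can be reached. The real split gave 1774 genes and the highest other 0 (1 of 10 splits had as many), with at most 7 genes at an unadjusted p of 0.05 by limma in the others. The study chose the list on these same libraries, and it held no change between -0.30 and 0.07 in the real split. That selection favoured the real split in advance, so its lead is not independent evidence of a change. For lists called by camera the real split gave 2 and the highest other 7, and 10 of 10 splits gave as many.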
